A study of Homo sapiens with 2 samples.

How the data were processed

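RNA was extracted with Trizol from FTC-133 human thyroid cancer cells transfected with a control siRNA or with siRNA against CHI3L1, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. There were 2 libraries, 1 per group, assigned to groups by their labels. Whether a library came from 1 culture or from pooled cultures is not given in the sources used here, nor are the time after transfection, the siRNA sequences or the strand setting of the counting. Of 71 genes that the naming rule took or that had large folds below it, 20 have an exon that overlaps an exon of another gene in the table, 19 on the opposite strand and 2 on the same strand. Without the strand setting, reads of a gene and an overlapping antisense gene cannot be told apart, and same-strand overlaps stay uncertain under any strand setting. The overlapping gene had more reads in the control siRNA library than the gene itself for CLDN7 (ELP5, opposite strand) and ITGA1 (PELO, same strand).

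The authors deposited 1 table of normalised values for 19362 Ensembl gene identifiers in both libraries. The submitters' processing notes name FastQC, MultiQC, Trimmomatic, HISAT2 and featureCounts and the genome build GRCh38, without versions, roles or order. The annotation release, the normalisation tool and the filter on low genes are not given in the sources used here. From the values, the deposited unit is CPM: each value is a whole number of reads plus 0.001, times a fixed step per library, with 1 read worth 0.0632 CPM in the control siRNA library and 0.0513 CPM in the CHI3L1 siRNA library. All values (100% in each library, within 0.01 read) gave whole reads in this way. Every gene in the table had at least 6 reads in at least 1 library, so genes below that were not analysed here. The recovered depth was 15837449 reads in the control siRNA library and 19467345 in the CHI3L1 siRNA library, and 74 and 63 genes had 0 reads. A count of 0 allows up to 3 reads, or 0.190 CPM and 0.154 CPM. The 10 genes with the most reads held 7.32% and 9.84% of reads.

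Gene symbols came from a table of Ensembl identifiers and from GENCODE release 29 on GRCh38. A symbol was found for 17229 identifiers, and 19315 were in that release, which also gave coordinates. Transcript length, GC content and coding length came from 1 annotated transcript per protein-coding gene, the principal one with the best support and then the longest. They were had for 12683 of the 14815 tested genes (85.6%). The mitochondrially encoded genes were left out of the length correction.

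Fold is the log2 ratio of CHI3L1 siRNA over control siRNA after adding a pseudocount of 1 CPM to each, which understates the difference of low genes. Genes with a mean of at least 1 CPM over both libraries were tested by a fixed rule of size, a fold of at least 2 in either direction, with no p-value. The plan set a mean of 50 for values on a read scale and a mean of 1 for CPM, and the values were CPM. Ratios in parentheses have 95% exact (Clopper-Pearson) intervals from the recovered reads, conditional on both reads together. They cover counting error only. No count model was run.

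Gene lists were fixed before the data were examined. The median log2 fold of a list with at least 3 measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. A member counts as higher or lower at 1.5-fold. Bootstrap intervals resample the members of a list (2000 draws) and show spread across genes, not counting error. The named genes, by a rule also fixed before the data were examined, are CHI3L1, the 12 highest and 12 lowest folds among genes with a symbol and a mean of at least 100 CPM, and up to 4 members with the largest absolute fold in each list outside the central 95% and in the lists on CHI3L1 receptors, thyroid differentiation, epithelial, mesenchymal and proteolysis genes. Other genes named were chosen after their values were seen, and the text says so or names them as a list's sole member past the mean filter.

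Alternatives set before the data were examined were pseudocounts of 0.5 and 10 CPM, scaling to equal totals, centring on genes with a mean of at least 50 CPM, a trimmed mean of log ratios, no mean filter, a mean of at least 10 or 200 CPM, folds of 1.5 and 3, and protein-coding genes only. Added after seeing the data were a correction for transcript length and GC content, a restriction to transcripts of at least 2000 nt, and counting intervals wholly beyond 2-fold. The correction subtracted a spline trend (5 degrees of freedom per term) in transcript length, GC content and coding length, fitted to coding genes in none of the lists. List members were also compared with their 5 nearest genes outside the lists in length, coding length, GC content and mean CPM, another check chosen after the data were seen.

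The steps were tested on simulated data drawn at both depths from the mean share of reads of each gene, with 200 genes planted higher or lower. The 2-fold rule found 97 of 98 genes planted at 4-fold and 90 of 96 planted at 3-fold, and 0 of 14649 unchanged genes. These draws held counting error only, with no variation between cultures and no length or GC trend. The 0 therefore does not measure how many of the genes past 2-fold in the real libraries come from such variation. The counting interval held a ratio of 1 for 95.7% of 14843 unchanged genes. A list shift planted on 60 genes drawn at random, on top of a trend with length alone across 12706 genes, was recovered at −0.48 on the log2 scale by the correction and at −0.48 against the nearest genes. This test does not cover lists at the extremes of length or GC content, nor annotated lengths that differ from the expressed ones. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, patsy 1.0.2 and matplotlib 3.10.9.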

Results

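FTC-133 is an established human cell line derived from a follicular thyroid carcinoma. RNA sequencing was done on FTC-133 cells transfected with a control siRNA (1 library) and on FTC-133 cells transfected with siRNA against CHI3L1 (1 library). CHI3L1 encodes chitinase-3-like protein 1 (YKL-40), a secreted glycoprotein that binds chitin and has no chitinase activity. The comparison asks which transcripts differ when CHI3L1 is silenced. The control siRNA library held 15837449 reads in 19362 genes and the CHI3L1 siRNA library 19467345, as recovered from the deposited normalised read counts (CPM). With 1 library per group, no difference has a replicate check, no p-value is given across genes, and each comparison is of these 2 libraries and not of the conditions. Intervals of read ratios are 95% intervals and cover counting error only. They may be too narrow, since no molecular identifiers are described. Intervals of list medians, of differences from nearest genes and of rho are 95% bootstrap intervals over the genes of a list. These show spread across genes, which are not independent replicates, and do not measure variation between cultures.

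CHI3L1, which the label names as the siRNA target, was lower in the CHI3L1 siRNA library, at 48.6 CPM (947 reads) against 140 CPM (2215 reads) in the control siRNA library. Its log2 fold was −1.51, and the ratio was 0.347 (0.321 to 0.374). The gene (ENSG00000133048) is protein coding and lies on the minus strand of chromosome 1, from 203178931 to 203186749 in GRCh38. With a correction for transcript length and GC content its log2 fold was −1.46.

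In the CHI3L1 siRNA library, 20 of 33 collagen and matrix genes and 16 of 30 hypoxia and glycolysis genes were at least 1.5-fold higher, with 1 lower in each list. Of genes of the amino acid stress response driven by the transcription factor ATF4, 13 of 31 were higher, 18 did not pass 1.5-fold and 0 were lower. At least 1.5-fold lower were 58 of 76 ribosomal protein genes and 25 of 43 genes for nuclear-encoded subunits of oxidative phosphorylation, with 0 higher. Of all 14815 tested genes, 1145 were at least 1.5-fold higher and 1988 at least 1.5-fold lower. FN1, which encodes fibronectin, had the most reads of any named gene and stood at 17407 CPM in the control siRNA library and 39639 CPM in the CHI3L1 siRNA library (log2 fold 1.19, and 0.74 after the length and GC correction). Short transcripts were lower as a class, with a median log2 fold of −0.62 for the 609 tested coding genes of at most 1000 nt. Groups outside the range of random lists are therefore given also with values after a correction for transcript length and GC content. That correction was chosen after the data were seen. With it, 7 of 33 collagen and matrix, 15 of 30 hypoxia and glycolysis and 12 of 31 ATF4 genes were at least 1.5-fold higher. At least 1.5-fold lower were then 33 of 76 ribosomal protein and 13 of 43 oxidative phosphorylation genes.

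Among 14815 genes with a mean of at least 1 CPM, 153 were at least 2-fold higher and 654 at least 2-fold lower in the CHI3L1 siRNA library, and the median log2 fold was 0.01. The counting interval lay wholly beyond 2-fold for 84 higher and 475 lower genes. After the correction, 122 of 12683 protein-coding genes were at least 2-fold higher and 173 at least 2-fold lower, against 143 and 549 of the same genes before it. Of these, 67 higher and 140 lower genes were past 2-fold both before and after.

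**Figure D1:**
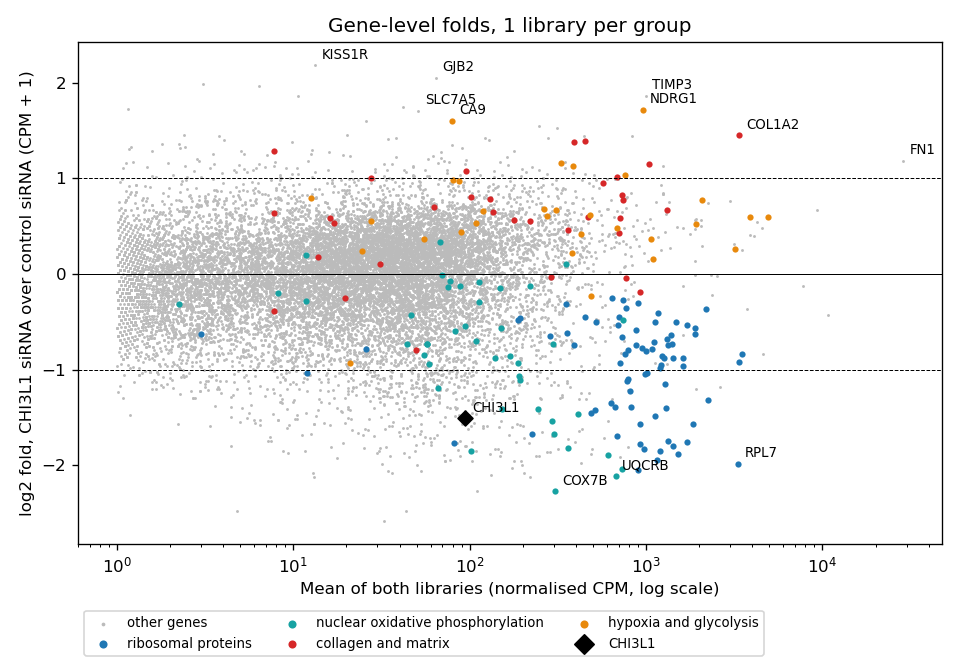
Mean CPM of both libraries (x axis, log scale) against log2 fold, CHI3L1 siRNA over control siRNA with 1 CPM added (y axis), for each of 14815 genes; colours mark 4 gene lists, the diamond marks CHI3L1 (log2 fold −1.51) and dashed lines mark 2-fold. Ribosomal protein genes lie below 0 (list median −0.87), and most collagen and matrix genes lie above it (list median 0.64).

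The 12 highest folds among genes with a symbol and a mean of at least 100 CPM included several genes of the extracellular matrix. TIMP3 (ENSG00000100234, chromosome 22, 32801701 to 32863043), a tissue inhibitor of metalloproteinases, stood at 429 CPM in the control siRNA library and 1561 CPM in the CHI3L1 siRNA library, a ratio of 3.64 (3.54 to 3.74). NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022), a hypoxia-responsive gene, stood at 446 and 1470 CPM, a ratio of 3.29 (3.21 to 3.38). The fibrillar collagen gene COL1A2 stood at 1814 and 4959 CPM, and LOX, whose product cross-links collagen, at 239 and 654 CPM. The log2 folds of the others were 1.55 for GANAB, a glucosidase II subunit, 1.53 for IGFBP5, 1.44 for COL11A1, 1.43 for LTBP1, 1.42 for MXRA5, 1.40 for APLN, the gene of the peptide apelin, 1.39 for COL8A1 and 1.38 for COL5A2. After the correction these 12 genes had log2 folds between 0.95 (COL5A2) and 1.74 (TIMP3).

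The 12 lowest folds under the same rule were of genes with coding sequences of at most 783 nt. COX7B (ENSG00000131174, chromosome X, 77899438 to 77907373), a subunit of cytochrome c oxidase, stood at 508 CPM in the control siRNA library and 104 CPM in the CHI3L1 siRNA library, a ratio of 0.205 (0.195 to 0.215). RPL7 (ENSG00000147604, chromosome 8, 73290267 to 73295789) stood at 5331 and 1343 CPM, a ratio of 0.252 (0.248 to 0.255). The log2 folds of the others were −2.27 for PFDN4, a prefoldin subunit, −2.12 for SNRPG and −2.09 for SF3B6, both of the spliceosome, −2.11 for UQCRB, −2.11 for SLIRP, −2.05 for RPL34, −2.04 for COX7C, −2.03 for PAGE2, −2.00 for ATP5MK and −1.98 for the proteasome subunit PSMA4. Reads of PAGE2 are uncertain, since a near-identical gene copy exists. After the correction the 12 genes had log2 folds between −1.99 (PSMA4) and −0.74 (ATP5MK).

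Of 37 gene lists fixed before the data were examined, 36 had at least 3 measured members, and the medians of 9 lay outside the central 95% of 10000 random lists matched on mean expression. For lists drawn at random, 1.8 would be expected there. The fixed lists differ from such lists, since some share genes and their members can vary together. The random lists were also not matched on transcript length or GC content, which folds followed. The 9 against 1.8 is therefore not a test. The collagen and matrix list had a median log2 fold of 0.64, at percentile 100, with 20 of 33 members at least 1.5-fold higher and 1 at least 1.5-fold lower. Its members include COL6A3 (4.11 CPM in the control siRNA library and 11.5 CPM in the CHI3L1 siRNA library). The mesenchymal list had a median of 0.39 (percentile 99.6), with 7 of 19 members higher and 1 lower by that rule. In it, CDH11, a cadherin of mesenchymal cells, had a log2 fold of 1.60, and LOXL2, another lysyl oxidase, of 1.05. The extracellular proteolysis list had a median of 0.50 (percentile 99.99), with 8 of 24 members higher and 2 lower. Beside TIMP3, ADAM19 and the protease inhibitor SERPINE2 had log2 folds of 0.98 and 0.96, while the collagenase gene MMP1 had 140 reads in the control siRNA library and 15 in the CHI3L1 siRNA library, a ratio of 0.0869 (0.0474 to 0.148).

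The integrin list had a median of 0.40 (percentile 99.8), with 7 of 19 members higher and 2 lower by 1.5-fold. The fibronectin receptor subunit ITGA5 stood at 490 and 1005 CPM, ITGA6 at 75.1 and 155 CPM, and ITGA1 at 3.60 CPM in the control siRNA library, with a log2 fold of 0.97, whereas ITGAE stood at 116 CPM in the control siRNA library and 29.2 CPM in the CHI3L1 siRNA library (log2 fold −1.95). The epithelial junction and keratin list had a median of 0.35 (percentile 99.8), with 4 of 14 members higher and 0 lower. Those members were CDH3 (log2 fold 1.08), CLDN1 (0.94), CLDN7 (0.77) and EPCAM (0.73), with means of at most 21.4 CPM. After the correction, the medians were 0.30 for collagen and matrix, with 7 of 33 members at least 1.5-fold higher, 0.47 for mesenchymal and 0.39 for proteolysis genes, still outside the range of their random lists. The integrin (0.20) and epithelial (0.20) medians were inside it. Against their nearest genes, epithelial members were 0.39 higher (bootstrap interval 0.15 to 0.67) and integrin members 0.14 higher (−0.19 to 0.49). The epithelial median was also inside its range at a mean of at least 10 CPM (0.19, 5 members). Other medians were inside their range at no smaller a value, with fewer members: 0.49 for integrins at a mean of at least 200 CPM (5 members), and 0.39 for mesenchymal (13 members) and 0.37 for epithelial genes (9 members) among transcripts of at least 2000 nt. The genes that random lists were drawn from were also higher there. The median of all tested genes was 0.13 at a mean of at least 200 CPM and 0.14 among those transcripts, against 0.01 in the main setting.

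The hypoxia and glycolysis list had a median of 0.59 (percentile 100), with 16 of 30 members at least 1.5-fold higher and 1 lower. Carbonic anhydrase 9 (CA9) stood at 39.1 and 121 CPM, carbonic anhydrase 12 (CA12) at 240 and 527 CPM, and the collagen prolyl hydroxylase subunit P4HA2 at 204 and 456 CPM. The ATF4 and amino acid stress list had a median of 0.50 (percentile 100), with 13 of 31 members higher and 0 lower. The amino acid transporter SLC7A5 stood at 23.5 and 78.9 CPM, SESN2 at 11.0 and 27.5 CPM, ALDH1L2 at 35.5 and 76.7 CPM, and VLDLR, which is also in the hypoxia list, at 53.9 and 107 CPM. After the correction, the medians were 0.58 for the hypoxia list, with 15 of 30 members higher, and 0.44 for the ATF4 list, with 12 of 31, and both stayed outside the range of their random lists. At a mean of at least 200 CPM the ATF4 list had 3 members, and its median of 0.27 was inside.

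The ribosomal protein list had a median log2 fold of −0.87 (percentile 0), with 58 of 76 members at least 1.5-fold lower and 0 higher. Ribosomal proteins made up 10.8% of reads in the control siRNA library and 5.39% in the CHI3L1 siRNA library. Besides RPL7 and RPL34, RPL30 and RPL31 had log2 folds of −1.95 and −1.88. Reads of these genes are uncertain where processed pseudogenes share their sequence. The nuclear oxidative phosphorylation list had a median of −0.73 (percentile 0), with 25 of 43 members lower and 0 higher. UQCRB stood at 1092 and 252 CPM, COX7C at 1176 and 285 CPM and NDUFA4 at 965 and 259 CPM. The 13 mitochondrially encoded genes had a median of 0.42 (percentile 94.1), on the other side of 0. After the correction, the medians were −0.50 for ribosomal proteins and −0.39 for nuclear oxidative phosphorylation genes, both still under the range of their random lists, and 33 and 13 members were at least 1.5-fold lower. The oxidative phosphorylation median was −0.25 for its 14 members with annotated transcripts of at least 2000 nt. It was −1.54 for its 13 members with a mean of at least 200 CPM. Both were under their range.

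**Figure D2:**
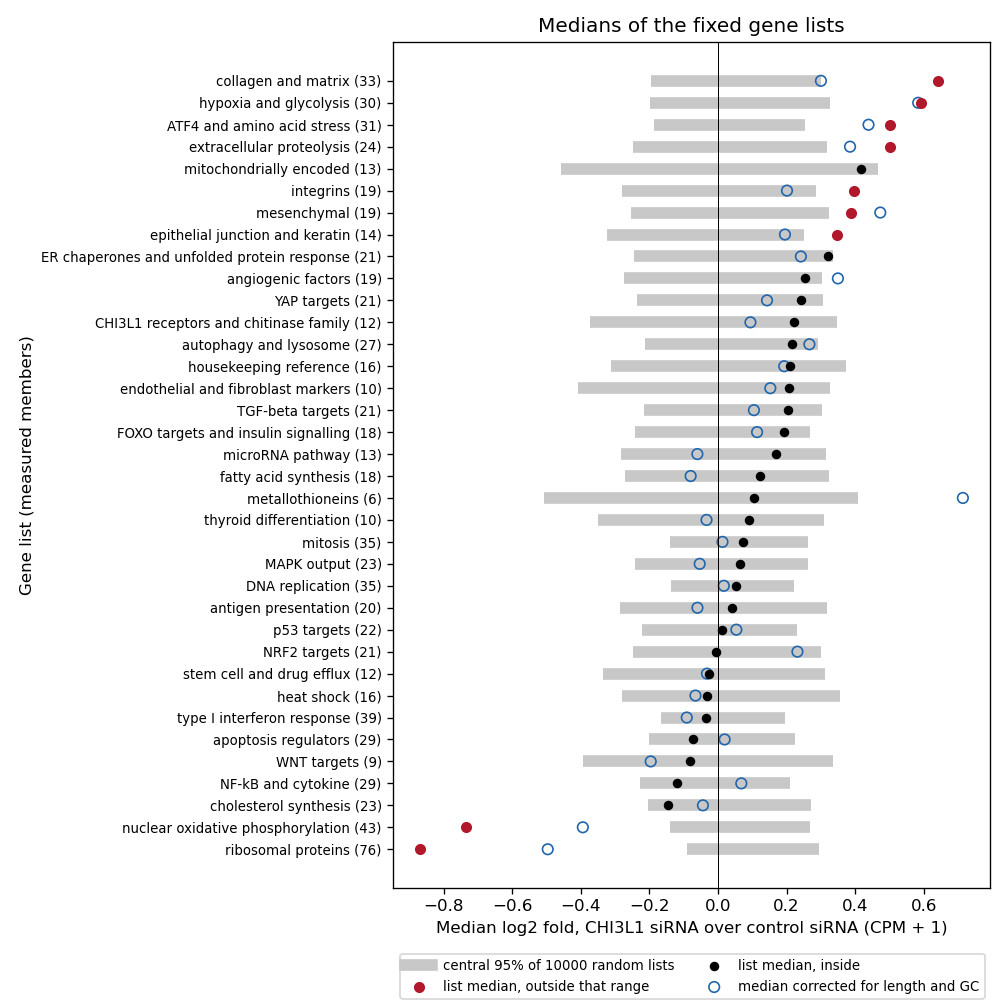
Median log2 fold (x axis, CHI3L1 siRNA over control siRNA, 1 CPM added) of each of 36 gene lists (y axis, measured members in parentheses). Filled points are medians, red where outside the grey bar (central 95% of 10000 random lists for uncorrected values), and open points are medians corrected for length and GC. Among the filled points, ribosomal proteins (−0.87) and collagen and matrix (0.64) are the ends.

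Thyroid differentiation genes had a median of 0.09 (percentile 68.7), and 0 of 10 measured members passed 1.5-fold on the log2 scale with 1 CPM added. The thyroid transcription factor NKX2-1 stood at 88.6 and 112 CPM, GLIS3 at 26.6 and 39.9 CPM, the thyroid hormone receptor THRB at 13.3 and 19.7 CPM and DUOX1 at 2.40 and 1.74 CPM, a ratio whose interval held 1 (0.443 to 1.18). Genes of reported CHI3L1 receptors and of the chitinase family had a median of 0.22 (percentile 86.1), with 1 of 12 members past 1.5-fold. That member was ITGAV (290 and 485 CPM), and ITGB3, CD44 and SDC1 had log2 folds of 0.40, 0.38 and 0.37. After the correction the median was 0.09, with 3 of 12 members past 1.5-fold (ITGAV, and IL13RA2 and CTBS, named after their values were seen), and ITGB3 and CD44 had log2 folds of 0.10 and 0.05. The corrected median of the thyroid list was −0.03, with 1 of 10 members at least 1.5-fold higher (THRB, log2 fold 0.62) and 1 lower (DUOX1, −0.64).

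The other lists lay inside the range of their random lists in the deposited values. Their medians were 0.32 for ER chaperones and the unfolded protein response, 0.25 for angiogenic factors, 0.24 for YAP targets, 0.22 for autophagy and lysosome, 0.21 for endothelial and fibroblast markers (10 of 14 measured, among them COL1A1 and COL1A2, which the collagen list also holds), 0.21 for the housekeeping reference, 0.20 for TGF-beta targets, 0.19 for FOXO targets and insulin signalling, 0.17 for the microRNA pathway, 0.12 for fatty acid synthesis and 0.10 for metallothioneins. The endothelial and fibroblast list was above its range at a mean of at least 10 CPM, where its 4 members were COL1A1, COL1A2, THY1 and LUM (median 0.78). Positive medians nearer 0 were 0.07 for mitosis, 0.06 for MAPK output, 0.05 for DNA replication, 0.04 for antigen presentation and 0.01 for p53 targets. Medians below 0 were −0.01 for NRF2 targets, −0.03 for stem cell and drug efflux, −0.03 for heat shock, −0.03 for the type I interferon response, −0.07 for apoptosis regulators, −0.08 for WNT targets, −0.12 for NF-kB and cytokine genes and −0.15 for cholesterol synthesis. Of 16 immune cell markers, 1 had a mean of at least 1 CPM (CD4, log2 fold 0.30), too few for a percentile. With no filter on the mean, 5 had a median of −0.32 (percentile 9.07), inside the range.

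Folds followed transcript length and GC content. Across 12683 protein-coding genes, the Spearman rho of log2 fold with transcript length was 0.46 and with GC content 0.10, across genes that are not independent replicates. The median log2 fold was −0.62 for 609 genes with transcripts of at most 1000 nt, −0.24 for 2493 genes above 1000 and up to 2000 nt, 0.03 for 4950 genes above 2000 and up to 4000 nt and 0.25 for 4631 longer ones. Genes at least 2-fold lower had a median transcript of 1519 nt with 41.8% GC, and those at least 2-fold higher 4605 nt with 50.9% GC, against 3145 nt and 48.8% over all. A smooth trend with transcript length, GC content and coding length took up 37.3% of the variance of folds across the coding genes in none of the lists, to which it was fitted.

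**Figure D3:**
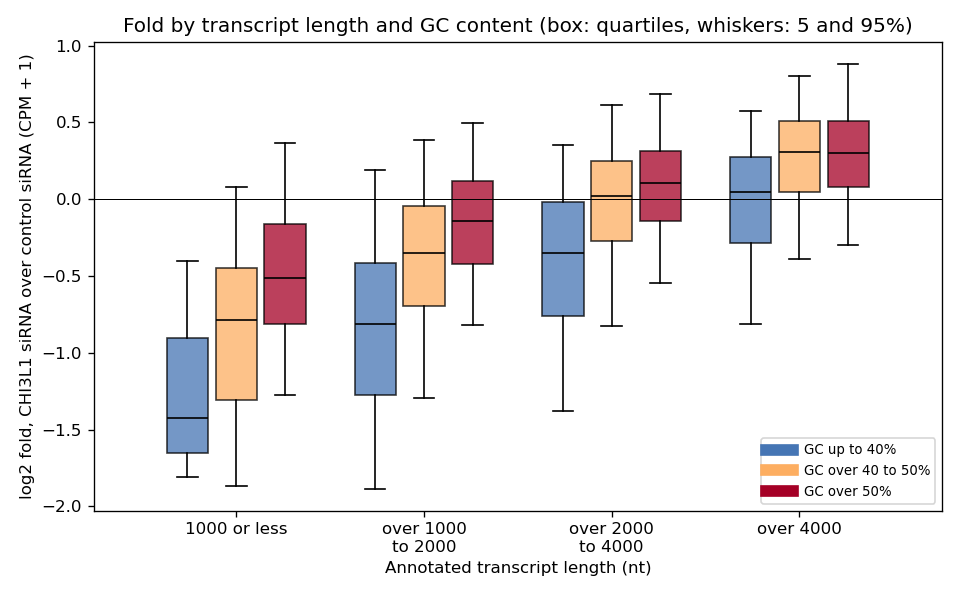
Log2 fold (y axis, CHI3L1 siRNA over control siRNA, 1 CPM added) of protein-coding genes by annotated transcript length in nt (x axis) and GC content (colours); boxes are quartiles with the median and whiskers the 5th and 95th percentiles of genes. Medians go from −1.43 in transcripts of at most 1000 nt with at most 40% GC to 0.31 in those over 4000 nt with over 40 to 50% GC. In those over 4000 nt with over 50% GC the median is 0.30.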

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

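The length and GC correction, the restriction to long transcripts and the counting intervals were chosen after the data were seen, and the other settings before. CHI3L1 stayed lower under each setting run, with its largest move at a pseudocount of 10 CPM (log2 fold −1.36). Counts of genes past 2-fold moved by over 1.5 times under several settings, each of which by its construction alters the folds, the rule or the genes tested. At a pseudocount of 10 CPM there were 53 higher and 327 lower genes, at a mean of at least 10 CPM 101 higher, and at a mean of at least 200 CPM 28 higher and 89 lower. The counts were 1145 higher and 1988 lower at 1.5-fold, and 12 higher and 135 lower at 3-fold. Counting intervals wholly beyond 2-fold left 84 higher genes. Centring moved the median log2 fold of all genes from 0.01 to −0.08 and left 94 higher genes. The length and GC correction left 173 lower genes, and transcripts of at least 2000 nt 198. Higher genes were 19.0% of those past 2-fold in the deposited values, 41.4% after the correction and 39.8% among transcripts of at least 2000 nt. The 9 lists outside their random range became between 8 and 12. Lost from the 9 were the epithelial list at a mean of at least 10 CPM, the integrin and ATF4 lists at 200 CPM (where the epithelial list had too few members), the epithelial and integrin lists after the correction, and the epithelial and mesenchymal lists among transcripts of at least 2000 nt. The medians of the integrin list at 200 CPM (0.49) and of the epithelial (0.37) and mesenchymal (0.39) lists in long transcripts were no smaller than in the deposited values, with fewer members. The median of all tested genes was higher under those settings, at 0.13 and 0.14 against 0.01. Gained, all above their range, were ER chaperones at a pseudocount of 10 CPM, at a mean of at least 200 CPM, among transcripts of at least 2000 nt and after the correction, endothelial and fibroblast markers at means of at least 10 and 200 CPM, angiogenic factors among those transcripts and after the correction, and autophagy, NRF2 and metallothionein lists after the correction. Of 89 recomputed medians of these 9 lists, 89 kept their sign, 81 stayed within the bootstrap interval of the reported value and 8 moved beyond it. Of the 27 lists inside their range, 16 changed sign under at least 1 alternative, 8 of them after the correction. No paired analysis was possible because each group has 1 library. Depth limits low genes most: 1 read was worth 0.0632 and 0.0513 CPM, and genes with few reads have wide intervals.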

Other observations

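The comparison with nearest genes, the fibroblast test and the genes named in the next paragraph were chosen after the values were seen. The length and GC correction was chosen after the length trend was seen, with its test on each list written before that list's corrected value. The fibroblast test replaced an earlier form that rested on LUM alone (ratio 0.776, 0.703 to 0.857), because the correction moved LUM to the other side of 0 (log2 fold from −0.36 to 0.16).

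Some genes between 10 and 100 mean CPM, which the naming rule leaves out, were singled out after their values were seen. KISS1R, the receptor of kisspeptin, stood at 4.17 CPM (66 reads) in the control siRNA library and 22.5 CPM (439 reads) in the CHI3L1 siRNA library, a ratio of 5.40 (4.16 to 7.10). The gap junction gene GJB2 stood at 24.3 and 104 CPM, a ratio of 4.28 (3.83 to 4.78), and the adenylate cyclase ADCY8 and the cyclooxygenase PTGS1 had log2 folds of 1.86 and 1.75. After the length and GC correction KISS1R and GJB2 stood at 2.27 and 2.24, and the other 2 at 1.52 and 1.44. On the other side, HMGN5, which encodes a nucleosome-binding protein, stood at 57.0 and 8.67 CPM. Its log2 fold was −2.59, and −1.67 after the correction.

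Lists inside the range of their random lists in the deposited values and outside it after the correction were angiogenic factors (corrected median 0.35), ER chaperones and the unfolded protein response (0.24), autophagy and lysosome (0.27), NRF2 targets (0.23) and metallothioneins (0.71, 6 members). The bootstrap interval of each reached into that range, from 0.13, 0.12, 0.14, −0.07 and 0.13 in the same order. Among transcripts of at least 2000 nt, the angiogenic (median 0.44) and ER chaperone (0.51) lists were also above their range. Examples of higher members, in deposited values and singled out after these were seen, are the chaperones HSPA5 (586 and 949 CPM) and CANX (467 and 799 CPM). Another is the lysosomal membrane gene LAMP1 (236 and 442 CPM). Before the correction, the ER chaperone and autophagy lists each had 6 members at least 1.5-fold higher and 2 lower. After it, ER chaperones had 5 higher and 0 lower, and autophagy 5 higher and 1 lower. NRF2 targets had 2 higher and 2 lower before it, and 3 and 2 after it. Metallothioneins have short transcripts, and MT2A stood at 235 and 224 CPM before the correction.

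The ribosomal protein and nuclear oxidative phosphorylation lists had medians under 0 in the CHI3L1 siRNA library. A dependence on transcript length and GC content, which RNA integrity or size selection could set, was tested by the correction. The medians stayed under their random lists at −0.50 (bootstrap interval −0.62 to −0.40) and −0.39 (−0.56 to −0.23). The 5 nearest genes of the members had medians of −0.58 and −0.49, and the members differed from those by −0.44 (−0.63 to −0.25) and −0.29 (−0.49 to −0.21). These values argue against the trend with annotated length and GC content as the whole cause. They do not settle a dependence on the expressed length, since both checks use annotated lengths. How much the trend adds stays open. The oxidative phosphorylation median was −0.25 among its 14 transcripts annotated at 2000 nt or more (−0.86 for 17 ribosomal proteins). This restriction also uses annotated lengths, so it cannot show that the expressed transcripts are long. Corrected folds of the oxidative phosphorylation genes still followed GC content (Spearman rho 0.48 across genes) and coding length (0.47). Those of the ribosomal protein genes still followed GC content (0.30). An annotated transcript can also be longer than the expressed one. UQCRB, annotated at 5575 nt with a coding sequence of 333 nt, moved only from −2.11 to −1.82. Reads shared with pseudogenes cannot be told apart for ribosomal proteins, where rho of fold with the number of pseudogenes was −0.29 (−0.49 to −0.06), and an effect of CHI3L1 silencing was not testable with 1 library per group.

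The collagen and matrix list had a median above 0 in the CHI3L1 siRNA library. Their transcripts are long, and the corrected median of 0.30 (0.17 to 0.40) has an interval that reaches into the range of random lists (up to 0.23), so the length and GC trend cannot be told apart from a difference of this list as a whole. Members were 0.26 above their nearest genes (0.01 to 0.37). Fibroblasts mixed into the culture could bring COL1A2. DCN and LUM, abundant in fibroblasts, together gained 0.318% of what COL1A2 gained after the correction (counting bounds −0.0117 to 0.728). DCN had 19 and 29 reads. These values argue against fibroblasts rich in DCN and LUM as that source, but the test was written after they were seen. Of the other markers, THY1 was higher (558 and 745 CPM, ratio 1.34 with an interval above 1), PDGFRB had a ratio of 1.11 (0.862 to 1.42) and PDGFRA had 9 and 2 reads. The biological explanation in the design, CHI3L1 silencing, stays open beside the trend.

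The hypoxia and glycolysis list and the ATF4 list had medians above 0 in the CHI3L1 siRNA library. Their corrected medians were 0.58 (0.40 to 0.64) and 0.44 (0.32 to 0.61), beyond the upper ends of their random lists (0.26 and 0.17). Members were 0.33 (0.24 to 0.42) and 0.53 (0.17 to 0.59) above their nearest genes. These values argue against the trend with annotated length and GC content as the whole cause. They do not settle a dependence on the expressed length, since both checks use annotated lengths. Corrected folds of the ATF4 list still followed coding length (Spearman rho 0.41 across genes), so a part of its shift may still come from the length and GC trend. A hypothesis is that cells in the CHI3L1 siRNA culture met lower oxygen or nutrient levels, through CHI3L1 silencing, an unintended siRNA target or culture density. These were not tested, since each would need further cultures.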
